A study of Mus musculus with 14 samples.

How the data were processed

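The series holds 14 samples from male C57BL/6 mice given saline (mock) or morphine sulfate by injection into the peritoneum; the labels state neither the dose nor the time of collection. Per the labels, 8 samples are Drop-seq libraries of the nucleus accumbens, 4 mock and 4 morphine, each made from 2 pooled mice. The other 6 are RNA-seq libraries of oligodendrocytes sorted from whole brains of mice of 70 days, 3 mock and 3 morphine. No number of pooled mice is recorded for them, so each column, numbered here as deposited, was taken as 1 mouse. Replicate numbers 1 and 2 of the Drop-seq groups came from mice of 37 to 45 days and numbers 3 and 4 from mice of 78 to 82 days, in both groups alike, so age was spread evenly over the groups. Per the labels' protocols, the tissue was dissociated with papain, and the RNA of sorted cells was amplified with a SeqPlex kit before reads of 50 bases were made.

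Per the file headers of the summary files, the authors made the Drop-seq values with DigitalExpression of the Broad Drop-seq tools. The deposited Drop-seq tables hold raw UMI counts per gene and cell barcode of 12 bases, where a UMI (unique molecular identifier) marks 1 captured transcript. They were checked against the summary files: in all 8 pools every barcode's sum equalled the listed total. Each table holds 3000 or 6000 barcodes. The deposited table of the sorted cells holds raw read counts per gene symbol without molecular identifiers. Per the submitters' processing notes, Trimmomatic 0.36, STAR 2.4.2a, HTSeq, DESeq2 and DESeq were used with build mm10 for the series, without saying which tool served which data. Per the file headers, another deposited table of the authors holds log2 fold changes with standard errors for the sorted cells, and raw and adjusted p-values; its log2 fold changes are positive where the count table has higher morphine columns. No source states whether reads were counted by strand, so a gene and an exon overlapping it on the other strand could not be told apart; of the 341 genes looked up, 94 have such an overlap and 26 overlap a gene on the same strand.

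Rows of the sorted-cell table that name no gene (no feature, ambiguous, not unique and the like) took 69.5% to 74.3% of all reads per library and were left out of library sizes and tests. The reads in genes numbered 21564115, 14989118 and 18479712 in mock mice 1 to 3 and 18972221, 18306640 and 23456702 in morphine mice 1 to 3. Mitochondrial genes took 15.0% to 16.9% of them. Intervals, standard errors and floors cover counting and replicate error only, since amplified reads are not independent molecules. A count of 0 was read as allowing up to 3 counts.

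Gene symbols of the replicate 1 pools came from another annotation than those of the other pools. In all, 1214 symbols were renamed to current ones through the reference's tables and 380 were merged, while 6121 symbols present only in replicate 1, with 0.765% of its UMIs, were left out of the comparisons; 2028 of the 33006 symbols of the sorted-cell table were renamed. Coordinates are from GENCODE vM21 on GRCm38 (mm10), counted from 1.

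Cells were processed in Python 3.11.15 with scanpy 1.11.5, numpy 2.4.6 and scipy 1.17.1. Barcodes with at least 300 detected genes and at most 20% mitochondrial UMIs were kept, 33225 of 36000. Scrublet was run per pool with an expected doublet rate of 0.05 and an automatic threshold, and the 881 doublets it called (2.65%) were removed after clustering. It called 0 in mock pool 1 and in morphine pool 2, 0.07% in morphine pool 1 and 0.17% in mock pool 3, so it did not work in those 4 pools and doublets remain there. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen across pools, and 30 principal components, 15 neighbours and Leiden clustering at resolution 1 with seed 0 gave 27 clusters. Clusters were named from marker lists into 16 classes, each of which stands for cells like those the markers name. The 5 clusters left unnamed (1902 cells, 5.9%) lacked enough of their own markers or mixed those of several classes. Of the barcodes kept, 1067 held an undetermined base and were treated like the rest.

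UMIs were summed per pool and class, for classes with at least 10 cells in at least 3 pools of each group, which left 15 classes; red blood cells were not tested. The ependymal class had 3 mock pools, the excitatory neuron class 3 morphine pools, and the perivascular macrophage class 3 pools per group. Each class, all cells together and the sorted cells were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr) without covariates, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed. Every adjusted p is from this test unless another tool is named. Whether the response differed between oligodendrocytes and another class was tested with a class by treatment term in edgeR, with the pool as a block. A score is the mean log2 CPM (counts per 1000000, prior count 1) over the tested genes of a list, 1 value per pool and class; scores, shares and quality measures were compared with exact permutation tests, two-sided, over 70 assignments of 8 pools. Their smallest p is 0.0286. For 3 against 3 samples it is 0.1.

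In the gene set tests, 23 lists were used: glucocorticoid-responsive genes, immediate early genes, myelin genes, cholesterol biosynthesis, heat shock, the unfolded protein and integrated stress response, hypoxia, p53 targets, interferon response, inflammatory cytokines and NF-kB, the circadian clock, insulin and FoxO response, opioid signalling, fatty acid oxidation and lipid storage, mitochondrially encoded genes, and markers of neurons, astrocytes, microglia, endothelial cells, mural cells, oligodendrocyte precursors, red blood cells, and ependymal and choroid plexus cells. Each was tested with camera of limma 3.58.1 at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the lists. Camera compares a list with all other genes; fry tests whether its genes move, on balance, 1 way. The lists, markers, filters, tests and the rule for named genes were fixed before the data were examined. That rule takes, in sorted cells and the oligodendrocyte class, the 12 largest called rises and falls whose groups do not overlap, 6 each in other classes, the 3 genes of smallest p where none is called, the 3 members of smallest p per list, and the opioid receptor genes; symbols beginning Gm or ending in Rik were passed over, and some results under this rule are not reported here. Adjustment over the 249 genes changed at least 2-fold in sorted cells, and gene names as deposited, were alternatives chosen after seeing the data.

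Alternatives were DESeq2 1.42.0, size factors of DESeq2, limma-voom, no filter or a filter of 20 counts, leaving out each replicate, the replicate number as a block, younger or older pools alone, an age covariate, at least 500 genes or at most 10% mitochondrial UMIs per barcode, doublets kept, sums thinned to the smallest pool, and classes from marker scores per cell. Each fit was tested on simulated data, counts drawn from the real means and library sizes with 200 genes changed. In the sorted-cell design 78.9% of 2-fold and 97.9% of 4-fold changes were recovered, and in the oligodendrocyte class 38.9% and 95.5%. Each gene was drawn independently, without variation that genes share between pools, so these shares do not give the power in the real data. In the real oligodendrocyte class Epb41l4a, Cdkn1a and Tma16 had log2 differences of 2.37 to 2.46 and were not called (adjusted p = 0.341 to 0.349). Counts between replicates of 1 group varied more than counting alone gives, with a chi-square over degrees of freedom of 20.6 to 65.1 among pools and 3.74 to 14.4 among sorted libraries.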

Results

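Single cells of the nucleus accumbens were profiled by Drop-seq, in which each cell meets a barcoded bead inside a droplet, after saline (mock) or morphine, with 4 pools of 2 mice in each group. Oligodendrocytes, the cells that form myelin, were sorted from whole brains of other mice, 3 per group, and their RNA was sequenced in bulk. The comparisons address which cell types of the brain change their transcripts after morphine, and in which genes. The mock pools gave 2885, 5450, 2870 and 5375 cells with 7910574, 13483155, 8757796 and 22946109 UMIs in replicates 1 to 4. The morphine pools gave 2849, 5700, 2746 and 4469 cells with 6751718, 19477366, 8033588 and 19956482 UMIs. The sorted libraries held 14989118 to 23456702 reads in genes.

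The 32344 cells, with a median of 2156 UMIs, fell into 16 classes named from their markers. Medium spiny neurons, the main neurons of the accumbens, made up the largest classes, 7505 cells of the D1 type and 4676 of the D2 type. There were 4032 astrocytes, 3750 oligodendrocytes, 2324 interneurons, 1570 endothelial cells, 1463 excitatory neurons, 1178 oligodendrocyte precursors and 1095 microglia. The smaller classes were 769 mural cells, 533 neuroblasts, 511 dividing progenitors, 492 newly formed oligodendrocytes, 305 ependymal cells, 128 red blood cells and 111 perivascular macrophages. No class differed in its share of cells between the groups (exact permutation test, adjusted p of 1 for all 16). Oligodendrocytes were 10.5% ± 3.74 of cells in mock and 12.6% ± 1.61 in morphine pools (SD, n = 4 each, exact permutation p = 0.343), a difference of 1.05 percentage points in the younger and 3.10 in the older pools. These shares depend on dissociation and on how many barcodes were deposited.

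Cells of the morphine pools held a larger share of mitochondrial RNA. The median per cell was 3.73% ± 0.665 in mock and 5.602% ± 0.979 in morphine pools (SD, n = 4 each, exact permutation p = 0.0286), higher by 1.295 points in the younger and 2.45 in the older pools. Among oligodendrocytes the medians were 3.75% ± 0.581 and 6.05% ± 1.17 (SD, n = 4 each, exact permutation p = 0.0286), with differences of 2.06 points in the younger and 2.525 in the older pools. The ribosomal RNA mt-Rnr2 had higher values in morphine pools in all 15 classes tested, by log2 0.62 to 1.29, while the median of the mitochondrial mRNAs lay between -0.24 and 0.193 across these classes. The counts of mt-Rnr2 are part of the mitochondrial share. Over all cells it stood at 18560 to 26000 CPM in mock and 33390 to 47330 CPM in morphine pools. Much of the larger share was therefore this RNA. In the sorted oligodendrocytes mt-Rnr2 did not change (log2 0.09, SE 0.052, adjusted p = 0.307).

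The first comparison asks what morphine changes in oligodendrocytes sorted from the brain. Genes that glucocorticoid hormones induce rose together, and 11 of 12 genes of the heat shock response fell. Cdkn1a, which encodes the cell cycle inhibitor p21, went from 6.49 ± 0.866 to 292 ± 20.8 CPM (mean ± SD, n = 3 mice per group), a 44.5-fold rise. Sgk1, a kinase induced by glucocorticoids, went from 103 ± 9.12 to 1619 ± 80.6 CPM, and Fkbp5, a chaperone that restrains the glucocorticoid receptor, from 9.31 ± 1.68 to 105 ± 4.61 CPM. Hspa1b, which encodes an inducible chaperone of the Hsp70 family, went down from 8.49 ± 0.812 to 0.484 ± 0.0534 CPM. Of 15759 genes tested with edgeR, 1275 rose and 1051 fell, of which 354 and 153 changed by at least 2-fold.

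Among the 12 largest rises, the log2 fold changes were 5.48 for Cdkn1a (SE 0.090, adjusted p = 1.66e-19), 3.98 for Sgk1 (SE 0.067, adjusted p = 1.66e-19) and 3.48 for Fkbp5 (SE 0.095, adjusted p = 3.01e-16). Sh2b2, an adaptor of receptor tyrosine kinases, rose by 4.94 (SE 0.128), from 2.03 ± 0.643 to 64.0 ± 3.35 CPM. Tma16, a factor of ribosome assembly, rose by 4.01 (SE 0.075), from 24.7 ± 2.48 to 397 ± 23.2 CPM. Zfand4, a zinc finger gene, rose by 4.35 (SE 0.113), and Plin4, which encodes a lipid droplet coat protein, by 3.33 (SE 0.108), from 23.5 ± 5.76 to 239 ± 12.6 CPM. The other rises of this size began near the floor of detection: Aire, Lancl3, Mchr1, Mrgpra6 and Mrgpra9 had 0.126 to 0.770 CPM in mock mice and 1.59 to 10.5 CPM in morphine mice. Mrgpra6 and Mrgpra9 belong to a family of near-identical receptors, so reads between its members are uncertain. Exons of Cdkn1a, Aire, Lancl3 and Plin4 overlap genes on the other strand, and the overlapping genes cannot be told apart.

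Among the 12 largest falls, Hspa1b fell by 4.12 on the log2 scale (SE 0.226, adjusted p = 1.86e-11) and its near-identical neighbour Hspa1a by 2.70 (SE 0.257, adjusted p = 8.16e-08), and reads between these copies are uncertain. Fbn2, which encodes the microfibril protein fibrillin 2, fell by 2.17 (SE 0.112, adjusted p = 7.19e-12), from 28.8 ± 3.39 to 6.38 ± 0.405 CPM. The other 9 had 0.764 to 1.22 CPM in mock mice and 0.0609 to 0.235 CPM in morphine mice, few reads each. Of these, the neutrophil granule gene Ngp, the receptor family gene Olfr305 and the lectin gene Cd209b stayed called without any single library. Leaving out 1 library ended the calls of the other 6. Mycn had adjusted p = 0.113 without mock 1 and 0.0614 without morphine 3. Vmn2r102, again of a near-identical family, had 0.0522 without morphine 1 and 0.0659 without morphine 2. Proz had 0.096 and 0.0675 without mock 1 and 3, and 0.12 and 0.169 without morphine 1 and 2. For S100a9 the values were 0.178 and 0.0969 without mock 1 and 3, and 0.204 and 0.237 without morphine 2 and 3. Mpig6b had 0.117 and 0.074 without mock 1 and 3, and 0.179 and 0.196 without morphine 1 and 2. For Enthd1 they were 0.0524 and 0.0618 without mock 2 and 3, and 0.135 and 0.0961 without morphine 2 and 3.

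The positions of the main genes on GRCm38 are, on chromosome 17, 29090976 to 29100727 for Cdkn1a, 28399094 to 28517527 for Fkbp5, 56100591 to 56109803 for Plin4, 34956436 to 34959238 for Hspa1b and 34969190 to 34972156 for Hspa1a. Sgk1 lies on chromosome 10 from 21882184 to 21999903, Tma16 on chromosome 8 from 66473118 to 66486530, and Sh2b2 on chromosome 5 from 136218147 to 136246556. Zfand4 lies on chromosome 6 from 116264222 to 116330302 and Fbn2 on chromosome 18 from 58008623 to 58210487.

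By gene list, the glucocorticoid-responsive genes were the clearest group in the sorted cells. Of 28 tested, 24 rose and 1 fell over all genes tested, and 25 rose and 1 fell when adjusted over the list alone. The median log2 change was 1.77 (camera adjusted p = 4.82e-134, adjusted p = 0.0124 with an estimated correlation, fry adjusted p = 0.000223). The rises included Nfkbia, the inhibitor of NF-kB, by 2.77, Zbtb16, a zinc finger repressor, by 2.75, and Per1, a clock gene that the hormone induces directly, by 1.39; Rhob fell by 0.24. All 4 were chosen after their values were seen.

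Chaperone genes went the other way. Of 12 heat shock genes, 0 rose and 11 fell, also when adjusted over the list alone, with a median of -0.72 (camera adjusted p = 2.2e-15). The call was lost with adjusted p = 0.14 with an estimated correlation, while fry gave 0.00226. Hsp90ab1, a cytosolic chaperone, went from 523 ± 25.5 to 316 ± 10.3 CPM and Hsph1 from 144 ± 3.96 to 82.9 ± 7.73 CPM. Of 14 unfolded protein and integrated stress response genes, 3 rose and 8 fell, and 9 fell when adjusted over the list alone. Their median was -0.58 (camera adjusted p = 1.26e-07), with adjusted p = 0.30 with an estimated correlation and fry adjusted p = 0.00462. Hspa5, the main chaperone of the endoplasmic reticulum, went from 494 ± 22.5 to 164 ± 8.93 CPM, Creld2 from 23.3 ± 1.94 to 9.71 ± 0.271 CPM, and Xbp1, a transcription factor of this response, from 35.9 ± 4.45 to 16.2 ± 1.08 CPM.

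For the remaining lists camera made no call, with adjusted p from 0.188 to 0.801. Myelin genes went both ways, 2 rising and 7 falling of 18 (8 falling when adjusted over the list alone): Mobp rose from 3374 ± 73.3 to 5056 ± 94.0 CPM, while Aspa and Ermn fell by 0.53 and 0.47 on the log2 scale. Of 22 cholesterol biosynthesis genes, Insig1 rose by 0.25 and Nsdhl by 0.27, and Sqle had -0.16 (adjusted p = 0.115). Among 13 p53 targets 4 rose, led by Sesn1 with 1.10, Ccng1 with 0.79 and Mdm2 with 0.35 (fry adjusted p = 0.00843). Of 17 fatty acid oxidation and lipid storage genes 3 rose and 2 fell (fry adjusted p = 0.00215), with rises of 1.11 for Ucp2, 2.17 for Plin5 and 0.49 for Cpt1a, the enzyme that admits fatty acids to mitochondria. Immediate early genes gave 2 rises and 2 falls of 14, with Arc down from 60.8 ± 6.19 to 25.96 ± 1.62 CPM, Jun at -0.58 and Zfp36 at 0.83; fry called the list as falling (adjusted p = 0.0216). Clock genes gave 3 rises and 4 falls of 15 (7 falls when adjusted over the list alone): Tef rose from 95.1 ± 4.14 to 197 ± 10.5 CPM, Cry2 by 0.65, and Clock fell by 0.32. Insulin and FoxO-responsive genes gave 4 rises and 4 falls of 15 (5 falls over the list alone), with Cited2 at 1.10, Foxo3 at 0.39 and Pik3ip1 at -0.41; the list's median of 0.024 and mean of 0.082 were positive while camera's direction was down. Of 14 hypoxia genes 2 rose and 3 fell (5 over the list alone), with P4ha1 at -0.92, Slc2a1, a glucose transporter, at 0.42, and Vegfa at -0.53. Opioid signalling genes gave 2 rises and 2 falls of 17: Gnao1 0.42, Adcy5 0.41 and Gnai1 -0.28 for the 3 of smallest p. None of 16 interferon response genes passed, with Stat2 closest (0.24, adjusted p = 0.0694), and of 6 cytokine and NF-kB genes Relb fell by 0.80 (adjusted p = 0.0469).

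Markers of other cell types show what else the sort carried. Of 12 endothelial markers 4 fell, led by Kdr, from 9.34 ± 1.76 to 3.46 ± 0.212 CPM, with Flt1 at -0.49 and Slco1a4 at -0.50. Of 12 microglia markers Cx3cr1 fell by 0.67 and P2ry12 by 0.59; the list's median was 0.098, its mean -0.01 and camera's direction down. Among 12 astrocyte markers Agt rose by 0.77, Fgfr3 by 0.50, and Slc1a3 fell by 0.29. Of 12 neuron markers Snhg11 fell by 0.24, and of 8 ependymal and choroid plexus markers Kl fell by 0.90. Precursor markers gave 1 rise and 1 fall of 8 (2 rises when adjusted over the list alone): Tnr rose by 0.65 and Sox10, a transcription factor of the whole oligodendrocyte lineage, fell from 346 ± 3.64 to 180 ± 3.20 CPM; the median was 0.20 and camera's direction down. None of 9 mural, 5 red blood cell or 7 mitochondrially encoded genes passed. The mural median was -0.042 and its mean 0.096.

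Of the genes called in the sorted cells, 2291 had groups that did not overlap, and among all genes tested this share was 29.1%, against the 10% that chance gives for 3 against 3. The authors' deposited table gives 1865 genes an adjusted p under 0.05, 1155 up and 710 down; 1771 of them were also called here, all in the same direction. Across 14886 genes, which are not independent replicates, the log2 fold changes of both sources had Pearson's r of 0.973.

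**Figure D1:**
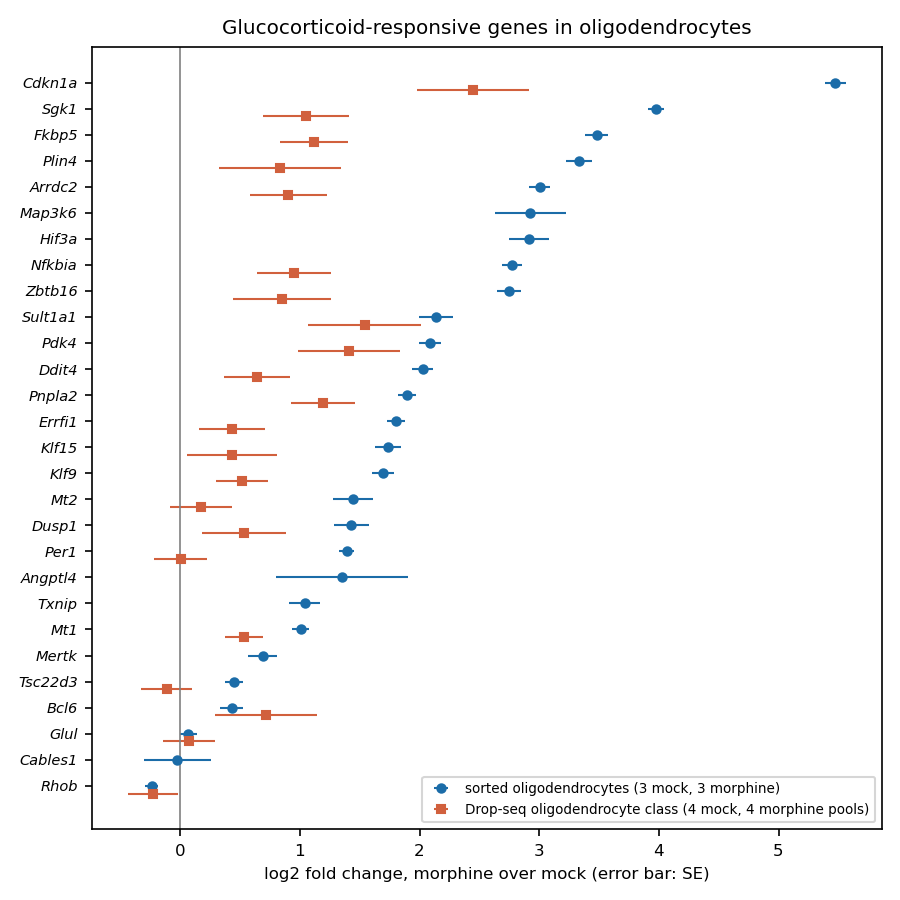
Log2 fold change (morphine minus mock, bars are ± 1 SE from edgeR) of the glucocorticoid-responsive genes in sorted oligodendrocytes (circles, 3 mice per group) and in the Drop-seq oligodendrocyte class (squares, 4 pools per group). Cdkn1a is highest in both, at 5.48 and 2.44, and in the sorted cells 24 of 28 genes rose.

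The second comparison asks whether the oligodendrocytes of the accumbens respond in the same genes. Without covariates no gene was called over all genes tested, and the genes changed most in the sorted cells mostly moved in the same direction. Cdkn1a stood at 211 ± 174 CPM in mock and 1164 ± 425 CPM in morphine pools (SD, n = 4), and Tma16 at 131 ± 77.8 and 684 ± 283 CPM. Of 201 genes raised at least 2-fold in the sorted cells and tested here, 198 (98.5%) were higher in the morphine pools, with a median log2 difference of 0.575. Of 48 genes lowered at least 2-fold, 35 were lower, with a median of -0.284.

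edgeR called 0 of 8694 genes in the oligodendrocyte class, and DESeq2 called 10. At an unadjusted p under 0.05 edgeR had 379, a smaller share than the 0.05 that chance alone gives. The genes of smallest p were Znfx1, a helicase (log2 1.18, SE 0.204, adjusted p = 0.341), Tma16 (2.37, SE 0.415, adjusted p = 0.341) and Rnpep, an aminopeptidase (0.91, SE 0.174, adjusted p = 0.349), each with all 4 morphine pools above all 4 mock pools; exons of Znfx1 and Rnpep overlap a gene on the other strand. All 10 calls of DESeq2 were rises: Tma16, Epb41l4a, Itgad, Phactr3, Znfx1, mt-Rnr2, Cdkn1a, Nt5c3, Pnpla2 and Rnpep, and all but mt-Rnr2 had risen in the sorted cells too (9 shared, 1.02 by chance, Fisher's exact p = 1.04e-08). Leaving out mock pool 4 gave edgeR 1 call, Cdkn1a. An age covariate gave it 6 calls, and the replicate number as a block 38, although the labels do not state pairing.

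Adjusted over the 249 genes changed at least 2-fold in the sorted cells, which are from other mice, 38 passed with edgeR, 36 up and 2 down, all in the direction of the sorted cells. The examples that follow were chosen after their values were seen. Epb41l4a, a gene of the band 4.1 family, rose by 2.46 (SE 0.478, adjusted p = 0.00999), Cdkn1a by 2.44 (SE 0.468, adjusted p = 0.00999) and Tma16 by 2.37 (SE 0.415, adjusted p = 0.00977). Phactr3, which encodes a regulator of protein phosphatase 1, rose by 1.52 (SE 0.312, adjusted p = 0.0113), from 562 ± 238 to 1622 ± 502 CPM, and Fkbp5 by 1.11 (SE 0.285, adjusted p = 0.0286). The falls were of Shtn1, by 0.70, and Insc, by 0.91. The count moved to 23, 12 and 13 without mock pools 1, 2 and 3, and to 9 and 16 without morphine pools 3 and 4; the highest with 1 pool left out was 50, without mock pool 4. It was 75 without a filter on low counts, 75 with an age covariate and 75 with classes from marker scores. With the replicate number as a block the count was higher still, as given below. The younger pools alone gave 8 and the older alone 23. The same adjustment gave at most 1 gene in each of the other 14 classes. Across the 8515 genes tested in both data sets, which are not independent replicates, Pearson's r of the log2 fold changes was 0.37 and Spearman's rho 0.247.

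**Figure D2:**
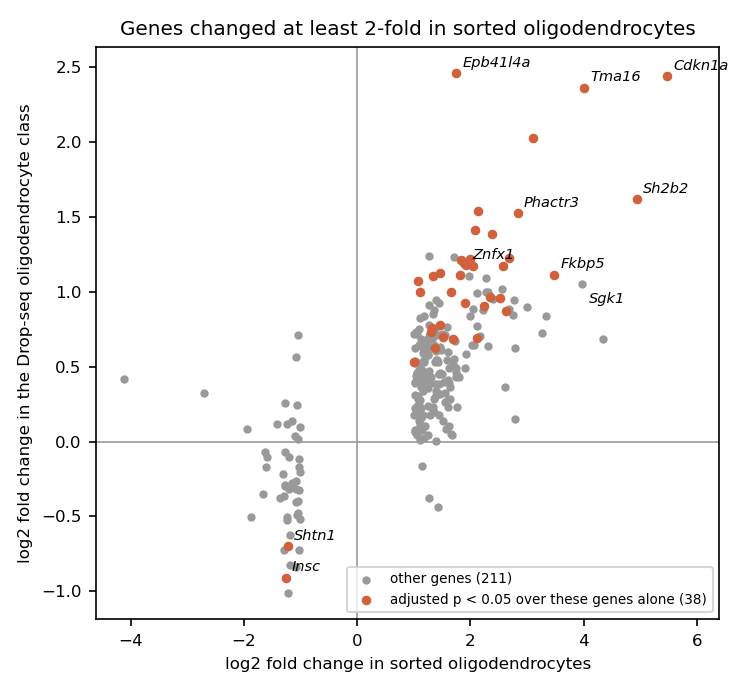
Log2 fold change (morphine minus mock) in the Drop-seq oligodendrocyte class, 4 pools per group, against that in sorted oligodendrocytes, 3 mice per group, for the 249 genes changed at least 2-fold in the sorted cells. The 38 genes that pass when adjusted over these genes are orange and the other 211 grey, and 198 of the 201 raised genes lie above 0.

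By gene list, 9 of 22 glucocorticoid-responsive genes rose in the oligodendrocyte class when adjusted over the list alone and 0 over all genes tested, with a median of 0.68 (camera adjusted p = 2.47e-18). This call was lost with adjusted p = 0.064 with an estimated correlation and fry adjusted p = 0.241. Besides Cdkn1a and Fkbp5, the list member of next smallest p was Pnpla2, which encodes a lipase of lipid droplets, at 41.4 ± 16 and 98.03 ± 20 CPM. Red blood cell genes were lower: 4 of 4 fell when adjusted over the list alone and 0 over all genes, with a median of -2.52 (camera adjusted p = 1.62e-14), lost with adjusted p = 0.064 with an estimated correlation. Among these globin genes Hba-a1 stood at 341 ± 231 and 59.1 ± 54.7 CPM and Hbb-bt at log2 -2.74. Of the 3750 oligodendrocyte barcodes, 10 in mock pools held 86.3% of the mock globin UMIs and 5 in morphine pools 46.1% of the morphine ones, and without these 15 the log2 ratio of globin CPM went from -2.25 to -0.489; 1 mock pool also stood apart in its share of red blood cells, at 1.73%. Myelin genes had a median of -0.155 (camera adjusted p = 0.00274, adjusted p = 0.726 with an estimated correlation), with Aspa at -0.51, Gjb1 at -0.37 and Opalin at -0.44, and cholesterol biosynthesis genes one of -0.199 (camera adjusted p = 0.0158, adjusted p = 0.726 with an estimated correlation), with Cyp51 at -0.57 and Msmo1 at -0.61. None of those 40 genes passed. The other 17 lists tested had camera adjusted p of 0.25 or more, and 1 of their genes, Ttr of the choroid plexus list, passed over its list alone. Heat shock genes, which fell in the sorted cells, had a median of 0.071 here (11 tested, 0 passed, camera adjusted p = 0.869); camera's direction was down against a positive median and mean, and the median and mean also differed in sign for the hypoxia, clock, endothelial and choroid plexus lists.

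Cdkn1a transcripts were spread over most oligodendrocytes of the morphine pools. With each cell thinned to 1000 UMIs, 16.5% ± 12.7 of oligodendrocytes held a Cdkn1a UMI in mock and 59.9% ± 8.76 in morphine pools (SD, n = 4 each, exact permutation p = 0.029). The highest mock pool had 34.9% and the lowest morphine pool 47.8%, and the unthinned means were 24.2% and 75.2%. Thinning left out 225 mock and 234 morphine oligodendrocytes with fewer UMIs. Tma16 was seen in 8.49% ± 3.87 and 31.3% ± 7.65 of oligodendrocytes, and Phactr3 in 35.6% ± 12 and 72.3% ± 8.20 (SD, n = 4, exact permutation p = 0.029 for each). D1 neurons, taken as background, held Cdkn1a in 3.01% ± 0.165 and 4.94% ± 1.52 of cells, and astrocytes in 5.91% ± 2.50 and 18.6% ± 4.30 (SD, n = 4, exact permutation p = 0.029 for each). Their groups did not overlap either: the highest mock and lowest morphine pools had 3.23% and 3.79% in D1 neurons, and 8.77% and 12.97% in astrocytes. The median depths were 1846 UMIs in oligodendrocytes, 1458 in astrocytes and 3228 in D1 neurons.

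The next comparison asks whether the response belongs to oligodendrocytes or to all cells. The genes raised at least 2-fold in sorted oligodendrocytes rose more in the oligodendrocyte class than in 13 of the 14 other classes. In oligodendrocytes their mean log2 CPM went from 5.18 ± 0.201 to 5.82 ± 0.153 (SD, n = 4 pools each), a difference of 0.635 (0.619 in the younger and 0.651 in the older pools). Newly formed oligodendrocytes had a difference of 0.298 (younger 0.363, older 0.232) and precursors one of 0.233 (0.184 and 0.282), the only other classes whose groups did not overlap. Each of these 3 differences had exact permutation p = 0.0286 and, over the 15 classes, adjusted p = 0.143. The difference between oligodendrocytes and another class was tested directly over the genes both share: it was 0.309 to 0.624 in 13 classes (exact permutation adjusted p = 0.0308 for each), and 0.198 for perivascular macrophages (exact permutation p = 1, with 3 pools per group). With the glucocorticoid list left out, the adjusted p was 0.0333 in 12 of those classes and 0.0615 for ependymal cells. In the scores of single classes without that list, precursors overlapped (0.194, exact permutation p = 0.0571) and endothelial cells did not (0.134, exact permutation p = 0.0286). The genes were chosen in sorted oligodendrocytes, which favours a larger difference in that class. The direct comparisons all use the same oligodendrocyte pools, so the 13 are not independent results. Perivascular macrophages, with 12 of the genes tested, had a score difference of 0.585 with overlapping groups. For the genes lowered at least 2-fold no such preference was seen. Their score differences ran from -0.353 to 0.166 over the 15 classes, with -0.283 in oligodendrocytes. None of the direct comparisons of oligodendrocytes with another class was called for them (exact permutation adjusted p of 0.4 or more).

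**Figure D3:**
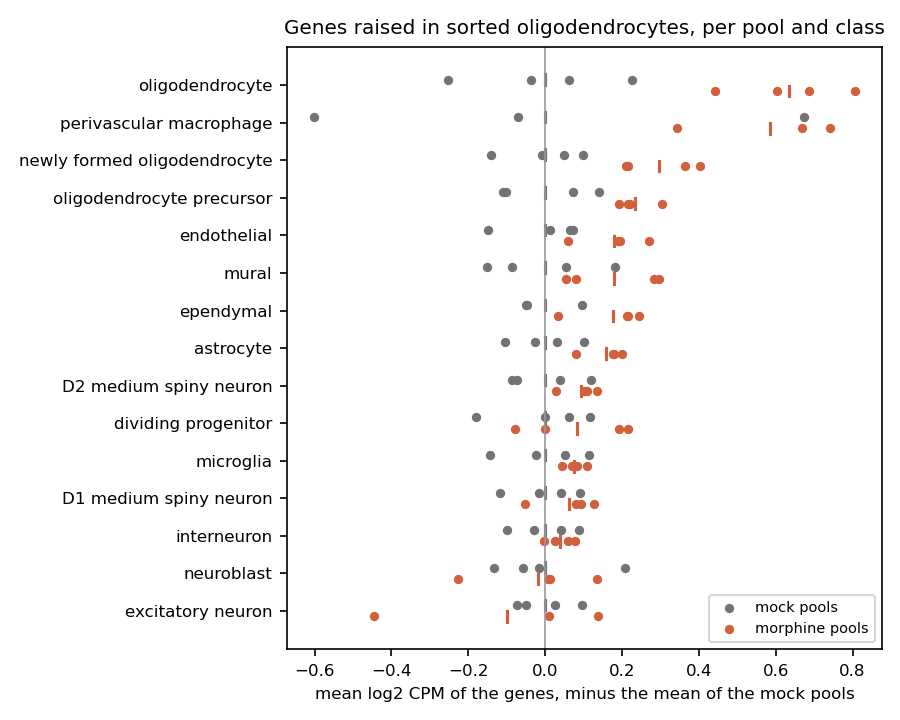
Mean log2 CPM of the genes raised at least 2-fold in sorted oligodendrocytes, per pool and Drop-seq class, minus the mean of that class's mock pools (points are pools, mock and morphine in different colours). Oligodendrocytes show the largest difference, 0.635, followed among classes without overlap by newly formed oligodendrocytes with 0.298 and precursors with 0.233.

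The glucocorticoid-responsive list was scored in the same way. Its mean log2 CPM was higher in the morphine pools in 15 of 15 classes, by 0.204 to 0.813. It went from 6.51 ± 0.455 to 7.32 ± 0.214 in oligodendrocytes (younger pools 0.798, older 0.828), from 7.09 ± 0.149 to 7.67 ± 0.304 in newly formed oligodendrocytes (0.720 and 0.442) and from 6.67 ± 0.124 to 7.19 ± 0.311 in precursors (0.529 and 0.522), with SD over n = 4 pools and exact permutation p = 0.0286 for each. Over the 15 classes the adjusted p was 0.143, so none passed. That is the smallest value these classes alone can reach, so it does not speak against a change. The difference between oligodendrocytes and each other class was not called for this list (exact permutation adjusted p of 0.514 or more), and the lists were not tested against each other.

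Gene by gene, the class by treatment test of edgeR called 9 differences over 14 pairs of classes. Of these, 3 were more positive and 6 more negative in oligodendrocytes. At an unadjusted p under 0.05 there were 4379, a smaller share of the genes tested than the 0.05 that chance alone gives. Tma16 rose more in oligodendrocytes than in newly formed oligodendrocytes (difference of log2 fold changes 1.62, adjusted p = 0.0105) and in dividing progenitors (2.84, adjusted p = 0.047), and Cdkn1a more than in ependymal cells (2.76, adjusted p = 0.0451). The 6 negative differences were of globin genes against endothelial, ependymal and microglial cells.

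The last comparisons ask what changed in the other classes and in the whole suspension. Cdkn1a was among the 3 genes of smallest p in newly formed oligodendrocytes, astrocytes, excitatory neurons, interneurons and all cells, always higher after morphine. Tsc22d3, an anti-inflammatory mediator that glucocorticoids induce, stood at 556 ± 157 and 1133 ± 234 CPM in astrocytes and at 508 ± 183 and 1115 ± 294 CPM in ependymal cells (mock and morphine, SD over 3 or 4 pools). No gene passed the test of edgeR in any of the 14 other classes or among all cells. At an unadjusted p under 0.05 there were 2064 over the classes and 246 of 15032 in all cells. Both are smaller shares of the genes tested than the 0.05 that chance alone gives. DESeq2 called 8 in the classes: mt-Rnr2 in 5, Cdkn1a in astrocytes and newly formed oligodendrocytes, and Malat1 in neuroblasts. It called 4 among all cells: Cdkn1a, mt-Rnr2, Tma16 and Itgad.

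Cdkn1a had a log2 difference of 2.54 in newly formed oligodendrocytes (SE 0.463, adjusted p = 0.106; 21.3 ± 12 against 140 ± 76.9 CPM), and leaving out morphine pool 2 made this a call. It had 1.69 in astrocytes (SE 0.284, adjusted p = 0.239), 1.52 in excitatory neurons (SE 0.257, adjusted p = 0.221), 1.32 in interneurons (SE 0.334, adjusted p of 1) and 1.74 in all cells (SE 0.252, adjusted p = 0.572), with Tma16 and Itgad next there. Mural cells were led by Sgk1 at 1.94 (SE 0.429), 45.5 ± 24 against 163 ± 70.8 CPM, then Mdp1 and Ppib, and excitatory neurons held Fos at 1.48 (SE 0.303) and Junb at 0.97 (SE 0.221), both immediate early genes of neuronal activity. The ribosomal RNA mt-Rnr2 was among the 3 in D1 neurons with Bloc1s1 and Synm, in D2 neurons with Tmf1 and Dcaf4, in interneurons with Otof, in dividing progenitors with Malat1 and Srek1ip1, in ependymal cells with Cdc14a, in perivascular macrophages with Foxp1 and H2-Eb1, and in astrocytes and newly formed oligodendrocytes, there with Map7d2. The remaining genes named by the rule were Ccdc90b, Rgcc and Gsta4 in endothelial cells, Tes, Pik3ip1 and Ccdc88a in microglia, Hba-a1, Hba-a2 and Nck1 in precursors, and Hbb-bs, Malat1 and Syne2 in neuroblasts. Without mock pool 4, Hbb-bs was called in neuroblasts.

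Lists show 2 themes outside oligodendrocytes. Camera called the glucocorticoid-responsive list as higher in 13 of 14 classes, neuroblasts being the exception, with medians of 0.101 to 0.723, and in all cells (median 0.362, adjusted p = 6.8e-28). With an estimated correlation or fry it was called in 0 of these classes; in all cells it had adjusted p = 0.121 with an estimated correlation. Adjusted over the list alone, 4 of its genes rose in astrocytes, 3 each in D2 and excitatory neurons, and 7 in all cells, against 0 over all genes tested. Immediate early genes were higher in excitatory neurons, where 6 of 14 rose when adjusted over the list alone (median 0.684, camera adjusted p = 2.41e-18, adjusted p = 0.052 with an estimated correlation), and in D1 neurons, where 3 of 16 did (median 0.336, camera adjusted p = 9.76e-07, adjusted p = 0.338 with an estimated correlation). In D1 neurons Junb stood at 91.7 ± 9.69 and 139 ± 23 CPM, and Arc, a regulator of synapses, at 25.97 ± 4.76 and 42.6 ± 9.40 CPM. By score, immediate early genes were higher in the morphine pools in 12 of 13 classes, and none passed (exact permutation adjusted p of 0.557 or more). The difference was 0.708 in excitatory neurons, the only class whose groups did not overlap, and 0.347 in D1 neurons. It was 0.498 in precursors and 0.490 in ependymal cells, and 0.061 in D2 neurons and 0.005 in interneurons. Classes were not tested against each other for this list, so whether the rise is particular to some of them stays open.

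Microglia markers were lower in all cells (median -0.593, camera adjusted p = 5.1e-15, adjusted p = 0.512 with an estimated correlation), and within microglia their median was -0.229 (camera adjusted p = 0.0089, adjusted p = 0.816 with an estimated correlation). In all cells camera also called endothelial markers (median -0.263, adjusted p = 0.746 with an estimated correlation), mural markers (-0.288, adjusted p = 0.746 with an estimated correlation), immediate early genes (0.262, adjusted p = 0.746 with an estimated correlation), and ependymal and choroid plexus markers (0.792, adjusted p = 0.52 with an estimated correlation). Among these choroid plexus genes Ttr stood at 12810 CPM in morphine pool 1 and at most 941 CPM in the other morphine pools, and the share of ependymal cells was 0.847% ± 0.753 in mock and 1.29% ± 0.711 in morphine pools (SD, n = 4, exact permutation p = 0.343; younger -0.23 and older 1.12 points). Neuron markers were lower in neuroblasts, 3 of 10 when adjusted over the list alone (camera adjusted p = 0.000775, adjusted p = 0.177 with an estimated correlation), and 3 of 3 red blood cell genes in precursors (camera adjusted p = 2.39e-05, adjusted p = 0.288 with an estimated correlation). Over the 14 classes camera made 37 list calls, and with an estimated correlation or fry 0.

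Of the opioid receptors, the kappa receptor gene Oprk1 had the most UMIs, 5425 over all cells, 2642 of them in D1 and 1178 in D2 neurons. The delta receptor gene Oprd1 had 530, with 290 in D2 neurons and 108 in interneurons, and Oprm1, the receptor through which morphine mainly acts, had 318, with 132 in D1 neurons, 66 in D2 neurons and 42 in interneurons. Where these genes were tested none changed, with adjusted p of 0.999 or 1. In D1 neurons Oprm1 had a log2 difference of -0.55 (SE 0.377) and Oprk1 one of 0.05 (SE 0.181). Oligodendrocytes held 5 Oprm1 UMIs in all, 0.582 CPM, where the level that 0 counts would allow is 0.349 CPM, and perivascular macrophages and red blood cells held 0, which allows up to 11.8 and 9.73 CPM. In the sorted oligodendrocytes Oprm1 was at 2.25 CPM in mock and 1.84 CPM in morphine mice (log2 -0.28, adjusted p = 0.633), and Oprk1 did not change either (0.03, adjusted p = 0.982).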

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

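Of the tests in this part, those of cell quality, astrocyte RNA, precursors and newly formed oligodendrocytes, mt-Rnr2 and globin barcodes, and the splits of the samples other than those of the class by treatment test, were chosen after the results were seen.

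The genes raised in sorted oligodendrocytes rose more in the oligodendrocyte class than in 13 other classes, a difference between groups of cells. The choice of these genes in sorted oligodendrocytes favours that class, and the 13 comparisons share its pools, so they are not independent. For the rise within oligodendrocytes alone, values argue against a higher mitochondrial share in the morphine pools as its whole cause. Among 1876 oligodendrocytes with 2% to 5% mitochondrial UMIs the score difference was 0.603, and among all 3750 it was 0.571. Both lack the TMM scaling behind the 0.635 reported above. The matched cells still had medians of 3.32% in mock and 3.84% in morphine pools. The mitochondrial share includes mt-Rnr2, so the matching was in part on that RNA. Other sides of cell quality, and their part in the difference between classes, were not tested. More astrocyte RNA in the morphine samples, as the source of the rise in oligodendrocytes, is also argued against. The higher median log2 change of the astrocyte markers, that of the sorted cells, was 0.065. Astrocyte RNA equal in both groups, with genes raised inside astrocytes, would leave the markers unchanged and was not tested. Among the 35 splits of the 8 pools, the real one called the most genes among those changed 2-fold in sorted cells, 38 (highest other 13). A share of 1 in 35 is the smallest these splits can give, so chance is made less likely but not excluded. A response of oligodendrocytes to morphine, or to hormones released after it, may be the source; the design holds no hormone measurement or receptor blockade, so these stay open.

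The glucocorticoid-responsive list was higher in the morphine pools outside oligodendrocytes too. Free RNA from broken oligodendrocytes is a candidate explanation, and its predicted shift lay below the lowest leave-one-out difference in 11 of 12 classes outside the lineage, with predictions of 0.004 to 0.09 against observed differences of 0.204 to 0.681. The exception was neuroblasts, with 4 genes of the list. For precursors the predicted shift was 0.019 and the observed 0.526. In newly formed oligodendrocytes the predicted shift was 1.21 and the observed 0.581, and since their level of oligodendrocyte markers was 99.4% of that in oligodendrocytes, free RNA and own transcripts cannot be told apart there.

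The ribosomal RNA mt-Rnr2 was higher in the morphine pools in all 15 classes. More mitochondrial RNA of every kind is argued against, because the median change of the mitochondrial mRNAs lay below 0.5 times that of mt-Rnr2 in 15 of 15 classes. A change that also occurs in sorted oligodendrocytes is argued against by the upper 95% limit of its log2 change there, 0.235. A difference in handling or priming between the pools may remain, which no label records, as does a biological difference between the accumbens and the whole brain, which was not tested.

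The class by treatment test gave 9 differences, for which chance cannot be excluded over the 35 splits, since other splits gave up to 923. The split of younger against older pools gave 767, while the 923 came from mock pools 2 and 3 with morphine pools 3 and 4, and 576 from mock pools 2, 3 and 4 with morphine pool 4, each with 3 of the 4 older pools on 1 side. Counts of this size point to a structure of the samples, and the splits do not separate age from other sources of it. Tma16 had differences of log2 fold changes of 1.62 against newly formed oligodendrocytes and 2.84 against dividing progenitors, and Cdkn1a one of 2.76 against ependymal cells. The globin genes had -3.21 (Hbb-bt), -3.07 (Hba-a1), -2.97 (Hba-a2) and -2.56 (Hbb-bs) against endothelial cells, -3.65 (Hba-a1) against ependymal cells and -2.57 (Hbb-bs) against microglia. In the oligodendrocyte class the log2 ratio of globin CPM was -2.25, and without 15 barcodes of at least 10 globin UMIs, 10 in mock and 5 in morphine pools, it was -0.489.

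The 10 splits of the 6 sorted libraries are too few for a share under 0.05: the real split called 2326 genes and the highest other 0, and for the glucocorticoid-responsive list the -log10 camera p was 134.7 and 8.55. For genes called over all genes in the oligodendrocyte class, in the other classes and in all cells, the real split gave 0. No split can give less, so the splits cannot test chance there. Other splits gave up to 306, 637 and 729. For the 379 oligodendrocyte genes of an unadjusted p under 0.05, chance cannot be excluded, since other splits gave up to 1708. The 306 and the 1708 came from the split of younger against older pools. The 637 came from mock pools 2 and 3 with morphine pools 3 and 4, and the 729 from mock pools 3 and 4 with morphine pools 2 and 4, each again with 3 of the 4 older pools on 1 side; the split by age gave 545 in the other classes and 0 in all cells. For the glucocorticoid-responsive list in the oligodendrocyte class, the camera call at the preset correlation had its largest -log10 p in the real split, 18.93. The highest other split gave 17.04, so chance is not excluded. That call was lost with adjusted p = 0.064 with an estimated correlation and fry adjusted p = 0.241, and the list's score had exact permutation adjusted p = 0.143.

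Single samples far from the others of their group were found 4 times in 86 groups tested, where chance gives 4.3. Morphine pool 4 kept 78% of its barcodes where the other morphine pools kept 93.8% to 95%, a gap of 0.929 of the range. Astrocytes were 10.2% of cells in 1 morphine pool and 12.3% to 12.6% in the others (0.876 of the range), and red blood cells 1.73% in 1 mock pool and 0.167% to 0.404% in the others (0.849). Ttr, a choroid plexus gene, stood at 12810 CPM in all cells of morphine pool 1 and at 0.1 to 941 CPM in the others (0.927).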

How the results depend on the processing

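The adjustment over genes changed at least 2-fold in the sorted cells, and gene names as deposited, were alternatives chosen after the results were seen. Of the values for single named genes and other results that do not answer a comparison by themselves, 1176 kept direction and side of the threshold over the alternatives, 51 passed it newly and 30 no longer passed. The only reversal was of Foxp1 in perivascular macrophages, at log2 0.493 with classes from marker scores per cell, and its cause was not tested. Of the 1176, 259 were of genes named in the sorted cells. The genes named in the Drop-seq classes and in all cells were not called at first, so for them keeping the side means staying uncalled.

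The count of genes changed in the sorted oligodendrocytes stayed within 1.5 times of 2326 under each alternative run: 2292 with size factors of DESeq2, 2261 without a filter, 2475 with a filter of 20 counts, 2049 with DESeq2, 2352 with limma-voom and 1765 to 2699 with 1 library left out. Of the 2326 genes, 2044 were called in the same direction with DESeq2 and 2269 with limma-voom.

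The oligodendrocyte class had 0 calls with edgeR, 379 genes at an unadjusted p under 0.05, and 34 calls without a filter, 10 with DESeq2 and 6 with an age covariate; with 1 pool left out it had 0 to 1, Cdkn1a without mock pool 4. The other classes had 0, with 2064 at an unadjusted p under 0.05, and 89 without a filter, 8 with DESeq2, and 1 each with younger pools alone (Ntng1 in excitatory neurons), doublets kept (Cdkn1a in astrocytes) and classes from marker scores (Cdkn1a in astrocytes). With 1 pool left out they had 0 to 1: Hbb-bs in neuroblasts without mock pool 4 and Cdkn1a in newly formed oligodendrocytes without morphine pool 2. All cells had 0, with 246 at an unadjusted p under 0.05, and 4 with DESeq2. The counts of 379, 2064 and 246 are each a smaller share of the genes tested than the 0.05 that chance alone gives. Genes called in both the sorted cells and the oligodendrocyte class numbered 0, and 9 with DESeq2 for both. The cause of these differences was not tested. The count of class shares called as different was 0 throughout, which a change in 1 class alone could not alter. The class by treatment test gave 9 calls, and 13 with sums thinned to equal totals.

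Of the genes changed at least 2-fold in the sorted cells, 38 passed in the oligodendrocyte class, 75 each without a filter, with an age covariate and with classes from marker scores. With 1 pool left out the count was 9 to 50: 23 without mock pool 1, 12 without mock pool 2, 13 without mock pool 3, 9 without morphine pool 3 and 16 without morphine pool 4. Younger pools alone gave 8 and older alone 23, with fewer samples in each.

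List calls depended on the test. Camera called 3 lists in the sorted cells, where an estimated correlation left 1 and fry called 6. In the oligodendrocyte class it called 4, in the other classes 37, of which 13 were the glucocorticoid-responsive list, and in all cells 6; with an estimated correlation each of these became 0, and with fry 0 as well. The first is wider by construction, since a list whose genes move together counts as fewer independent genes.

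Scores of the glucocorticoid-responsive list kept their direction with any pool left out, at 0.611 to 0.948 in oligodendrocytes, 0.475 to 0.674 in newly formed oligodendrocytes and 0.401 to 0.619 in precursors. The exact permutation p rose to 0.0571 in oligodendrocytes without each of the 4 morphine pools, and to 0.0571 or 0.0857 in the other 2 classes without each of the 4 mock pools. The cause was not tested.

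Replicate numbers were checked for pairing: the log2 values of mock and morphine samples of the same number, each relative to its group, correlated across genes with r of 0.028 to 0.465 in the oligodendrocyte class and -0.125 to 0.016 in the sorted cells, against -0.437 to 0.394 and -0.109 to 0.122 for different numbers, with means of 0.336 and -0.113 in the oligodendrocyte class. Mock pool 2 and morphine pool 2 (r of 0.028) each correlated better with another number, and the other 6 pools best with their own. Same-numbered pools share an age range in the labels, which name no shared litter, batch or day, so the samples were not treated as paired. With the replicate number as a block the oligodendrocyte class had 38 calls, the other classes 23, the genes changed 2-fold in sorted cells 108, and the sorted cells 2202. The list scores stayed at 0.813, 0.581 and 0.526 with exact sign-flip permutation p = 0.125, the smallest that 4 pairs can give.

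Recovery of 2-fold changes in simulated data ran from 8.6% in microglia and 9.4% in perivascular macrophages, the classes with the largest variation between pools (common biological coefficient of variation 0.317 and 0.42), to 68.8% in D1 neurons. The deepest classes, D1 and D2 neurons with 30323655 and 18291321 UMIs, had the highest recovery (64.3% in D2 neurons), and perivascular macrophages had the fewest UMIs, 253566. Between these the order was not that of depth: neuroblasts with 817568 UMIs had 48.8%, and oligodendrocytes with 8591595 UMIs had 38.9%. Younger or older pools alone could not be fitted for 3 classes: ependymal cells and excitatory neurons in the older, and perivascular macrophages in the younger pools.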

Other observations

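Of the tests in this part, the one along the oligodendrocyte lineage was chosen after the results were seen. Nr3c1, the gene of the glucocorticoid receptor, fell in the sorted oligodendrocytes from 129 ± 3.15 to 95.8 ± 7.55 CPM (SD, n = 3 mice each, log2 -0.43, SE 0.064, adjusted p = 3.61e-05), and it was chosen after its values were seen. Nr3c2, the gene of the mineralocorticoid receptor, which binds the same hormones, did not pass (log2 -0.02, SE 0.135, adjusted p = 0.945). In the Drop-seq oligodendrocyte class Nr3c1 stood at 181 ± 52.3 and 162 ± 54.9 CPM (SD, n = 4 pools each, adjusted p = 0.999), and in D1 neurons at 117 ± 17.4 and 109 ± 26.4 CPM (adjusted p of 1).

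The oligodendrocyte lineage runs from precursors over newly formed to mature oligodendrocytes. Whether the response to morphine grows with maturity stays open. The sorted-cell genes cannot decide it, since they were chosen in oligodendrocytes. For the glucocorticoid-responsive list, over only those of its genes that both classes share (12 with newly formed oligodendrocytes, 14 with precursors), the difference in oligodendrocytes exceeded that in newly formed oligodendrocytes by 0.133 and that in precursors by 0.0331, and the larger of the exact permutation p values was 0.8286. Precursors and newly formed oligodendrocytes were not tested against each other.

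Another hypothesis was that the 2 clusters of mature oligodendrocytes, of 2421 and 1329 cells, respond differently. The rise of the sorted-cell genes was 0.557 in each, and the exact permutation p of the difference was 1. A test of this size cannot show that they are alike.

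For Cdkn1a the hypothesis was that its rise may be spread over many oligodendrocytes. At 1000 UMIs per cell the lowest morphine pool had a Cdkn1a UMI in 47.76% of oligodendrocytes and the highest mock pool in 34.9%, so the shares of the groups do not overlap.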
